A study of Mus musculus with 15 samples.

How the data were processed

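The series measured gene expression in macrophages sorted from mouse ear skin, in 15 RNA-seq libraries of 5 groups with 3 libraries each. Per the labels' protocols, the mice carried a GFP reporter and a tamoxifen-inducible Cre recombinase at the Cx3cr1 locus together with a Cre-dependent tdTomato reporter, tamoxifen was given 3 weeks before the left ear was punched, and skin was taken 10 days after the punch. Cells positive for CD11b and CD64 and negative for lineage markers were sorted, per the labels' protocols, from the punched left ear and the unpunched right ear. The gates were GFP-negative, Tomato-negative for interstitial macrophages, GFP-positive, Tomato-positive for resident nerve-associated macrophages and GFP-positive, Tomato-negative for nerve-associated macrophages recruited after injury. Complementary DNA was made from 250 pg of RNA with the SMARTer Ultra Low Input kit and 13 PCR cycles, followed by Nextera XT library preparation, per the labels' protocols.

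Each library's group was taken from its title: interstitial macrophages of the unpunched ear (IM) and of the punched ear (injIM), the libraries titled sNAM without (sNAM) and after injury (injsNAM), and recruited sNAM after injury (recsNAM). The reporter field of the labels follows the treatment and not the population: injIM libraries carry the tag GFP-positive, Tomato-positive and sNAM libraries of the unpunched ear carry GFP-negative, Tomato-negative, against the titles and the sorting gates. The genotype field names Cxcr1 where the protocol names CX3CR1. The columns of injIM replicates 2 and 3 are spelled injM in the table. All libraries came from 3 mice, per the series' design, and the labels do not say which library came from which mouse. The groups therefore share animals, while the tests treated the 15 libraries as independent.

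Per the submitters' processing notes, bcl2fastq 2.18, cutadapt, STAR 2.7.2b, R 3.6.1 and DESeq2 1.24.0 were used with genome build mm10; the read counter, the gene annotation and the strand setting are not given in the sources used here. The deposited values are a signal per gene and library: read counts that the authors divided by 1 factor per library, in a table that is called counts but holds values that are not whole. In every library, 100% of the values above 0 lay within 0.01 of a whole multiple of the library's smallest value, so whole reads were recovered by dividing by that value. The recovered depth, in M reads (M, 10 to the power of 6), was 20.6 to 23.8 M for IM, 20.4 to 21.9 M for injIM, 5.64 to 18.6 M for sNAM, 16.9 to 19.5 M for injsNAM and 20.4 to 23.4 M for recsNAM. The libraries hold PCR-amplified reads without molecular identifiers, so reads are not independent molecules. No 2 libraries of a group agreed within read-sampling noise, the lowest chi-square per degree of freedom being 34.88. Amplified repeats of 1 RNA would also exceed that noise, so this does not exclude repeats, and each library was counted once, as the labels give it. The table lists 42454 entries, of which 36134 matched a symbol in the RefSeq annotation of GRCm38, the assembly that mm10 names, and coordinates are given on that assembly. Some symbols are listed more than once in the table, and each such gene is treated as uncertain.

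The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The planned test was edgeR's quasi-likelihood test on counts. It was replaced as the principal test because the deposited values are normalized, and it was run on the recovered reads as an alternative. The replacement was limma-trend with robust empirical Bayes moderation on log2(deposited value + 100), for the 8656 genes with a mean deposited value of 100 or more over the 15 libraries, with 1 mean per group and 1 array weight per group (IM 3.43, injIM 3.21, sNAM 0.175, injsNAM 0.311, recsNAM 1.67). The group weights, the pseudocount and the filter were chosen after the data were examined, because the sNAM and injsNAM libraries varied far more than the others. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(value + 100) scale understate the change of low genes; fold values given as such are ratios of group means.

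The fit was tested on simulated data built on the real genes. Within a group, simulated genes of equal mean had equal spread, and libraries were drawn independently. Spread particular to a gene and effects of shared mice were not simulated, so the rates below may differ from those in the real data. With no gene changed, it called on average 11.9 genes for sNAM against IM, 3.8 for injIM against IM, 1.2 for injsNAM against sNAM, 3.9 for injsNAM against injIM, 2.4 for recsNAM against injsNAM, 8.3 for recsNAM against injIM and 1 for the interaction, over 10 rounds of 8656 genes. A limma fit with 1 pooled spread called 636.3 unchanged genes for sNAM against IM and 457.6 for injsNAM against sNAM, and planned edgeR, on 13678 genes, called 157.7 and 545.9. Both called 0 for injIM against IM and for recsNAM against injIM, fewer than the fit with group weights, and planned edgeR called 52.4 for the interaction. Of simulated 4-fold changes, the fit with group weights recovered 4% for sNAM against IM, 93% for injIM against IM, 1% for injsNAM against sNAM, 24% for injsNAM against injIM, 22% for recsNAM against injsNAM, 80% for recsNAM against injIM and 0% for the interaction. Planned edgeR recovered 13%, 6%, 31%, 14%, 11%, 4% and 5% in the same order, and the pooled spread 28%, 7%, 27%, 7%, 22%, 4% and 0%. With these changes planted for injsNAM against sNAM, planned edgeR also called 606 unchanged genes, the pooled spread 536 and the fit with group weights 1.

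Genes were named by a rule: per comparison, the 8 higher and 8 lower called genes with the largest log2 change whose values did not overlap between the groups and whose mean in the higher group was at least 20 CPM, leaving out predicted genes, pseudogenes and receptor segments; then up to 4 called members of each list with the smallest adjusted p, or, where none was called, up to 2 members with the highest mean. The text gives a part of these genes, and some are not reported here. Of 32 gene lists, 22 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. The planned fry test of limma, which tests a list without setting it against other genes, was run beside camera and adjusted likewise. Counts of called members were also taken adjusted over the list alone. Lists of markers of other cell types were summed per library in CPM, reads scaled to a common total per library, and again without the gene of the list with the highest group mean.

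A steady-state signature was made from a fit of the 6 IM and sNAM libraries alone and scored in the other 9 libraries as the mean log2 value of sNAM-high genes minus that of IM-high genes, with exact 2-sided permutation tests between groups; with 3 libraries against 3 the smallest p is 0.1. The alternatives were edgeR as planned and with the deposited factors, DESeq2, limma voom with quality weights per library, 1 pooled spread, no filter, a pseudocount of 10, TMM scaling, only the compared groups in the fit, the replicate number as a block, and each library left out in turn. The p-values measure the spread between these libraries. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Overlaps between comparisons that share libraries were left out, because shared libraries alone raise them.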

Results

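Macrophages of mouse ear skin were profiled by RNA-seq 10 days after a punch through the left ear, with the right ear of the animals as the uninjured side. The 15 libraries formed 5 groups of 3: interstitial macrophages of uninjured (IM) and injured skin (injIM), nerve-associated macrophages of uninjured (sNAM) and injured skin (injsNAM), and nerve-associated macrophages recruited after injury (recsNAM). Values are normalized counts, the authors' read counts divided by 1 factor per library, given as mean ± SD with n = 3 libraries per group unless stated. Where a gene list's text names a library left out or the replicate block, the value beside it is the list's camera adjusted p under that setting. Recovered depth was 20878233, 23794162 and 20619909 reads in IM replicates 1, 2 and 3, and 20740448, 20397849 and 21931446 reads in injIM. It was 18632984, 5636251 and 9086996 reads in sNAM, 18785315, 16889283 and 19520105 in injsNAM, and 20970433, 20442263 and 23420175 in recsNAM.

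Cx3cr1, the fractalkine receptor gene whose locus carried the sorting reporter, was low in most libraries. It measured 3.38, 10.2 and 0 normalized counts in IM replicates 1, 2 and 3, 0.821, 7.28 and 23.5 in injIM. It measured 1.93, 0 and 27.8 in sNAM, 66.9, 0 and 0 in injsNAM, and 173, 96.7 and 160 in recsNAM. The gene was below the filter for testing. Because sorting used its reporter it checks the labels only weakly. GFP and the Cre recombinase were both inserted at this locus. Few reads of the gene therefore do not show that the locus was silent or that the sort failed. Pan-macrophage markers summed to 20360 ± 886 CPM, reads scaled to a common total per library, in IM, 19530 ± 1270 in injIM, 15490 ± 1280 in sNAM, 19510 ± 2450 in injsNAM and 20390 ± 1370 in recsNAM. The resident nerve-associated libraries were of lower complexity. In all, 10760 ± 1930 genes were detected in sNAM and 11430 ± 754 in injsNAM, against 15380 ± 176 in IM, 16190 ± 195 in injIM and 14340 ± 665 in recsNAM. The correlation between replicates was 0.644 to 0.776 in sNAM and 0.762 to 0.772 in injsNAM, against 0.972 to 0.982 in IM, 0.966 to 0.983 in injIM and 0.934 to 0.956 in recsNAM.

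**Figure D1:**
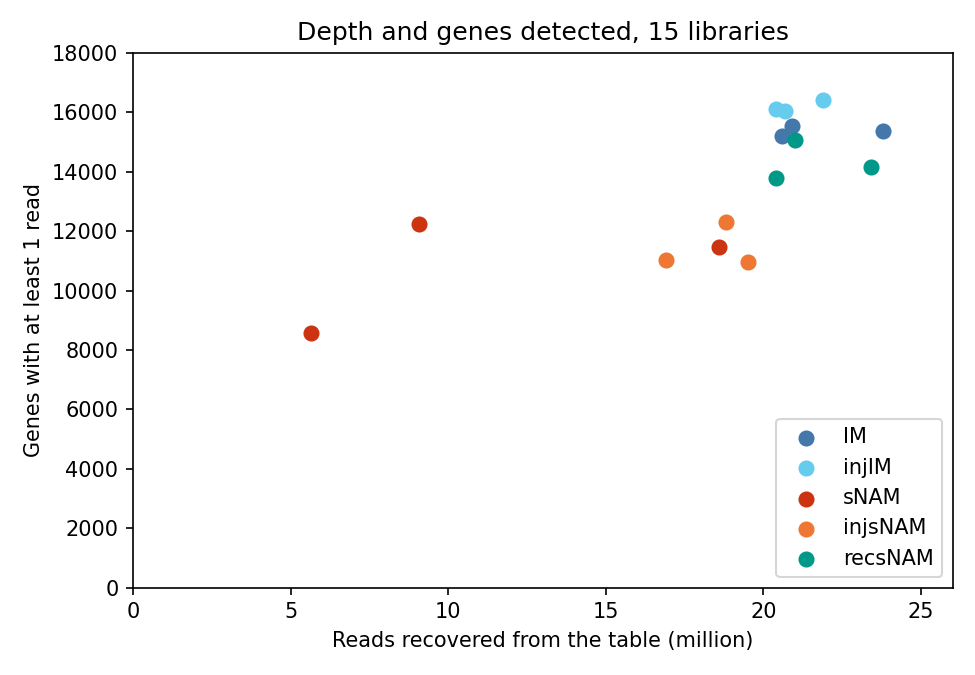
Genes with at least 1 read (vertical axis) against recovered reads (horizontal axis, in M reads, 10 to the power of 6); each point is 1 of 15 libraries, coloured by group. The sNAM and injsNAM libraries lie between 8581 and 12302 genes, below every library of the other groups, and sNAM replicate 2 is the shallowest at 5636251 reads.

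The comparison of sNAM with IM asked how nerve-associated macrophages differed from interstitial macrophages in uninjured skin. Ccr7, the chemokine receptor that guides migration towards lymph nodes (chromosome 11, 99144199 to 99155077, mm10), was 59.3-fold higher in sNAM (26810 ± 12500 against 452.2 ± 155, log2 difference 5.55, SE 0.82, adjusted p = 0.00494). Timd4, a phosphatidylserine receptor of resident macrophages (chromosome 11, 46810786 to 46844333), rose from 254.2 ± 166 in IM to 10440 ± 2320 in sNAM (log2 difference 4.97, adjusted p = 0.0131). Axl, a receptor tyrosine kinase for the uptake of dying cells (chromosome 7, 25756500 to 25788924), was 7.52-fold higher (9217 ± 4340 against 1226 ± 377, adjusted p = 0.0147). Its ligand Gas6 (chromosome 8, 13465374 to 13494535) fell from 17880 ± 959 to 4311 ± 1260 (adjusted p = 0.00734). Flt3, the receptor for a dendritic cell growth factor, measured 2347 ± 958 against 22.64 ± 10.9 (adjusted p = 0.0103). Cd74, the invariant chain of MHC class II (chromosome 18, 60803849 to 60812652), measured 551800 ± 184000 against 92550 ± 15900 (adjusted p = 0.0376). Lower in sNAM were the lysosomal proton pump subunit Atp6v0d2 (277.6 ± 476 against 4387 ± 838), and the endothelin receptor Ednrb (1469 ± 2070 against 8821 ± 1660). The endosomal RNA sensor Tlr7 (198.7 ± 341 against 2181 ± 135), the iron exporter Slc40a1 (198 ± 304 against 1853 ± 108) and Cd4 (673.5 ± 781 against 6184 ± 473) were lower too. Adjusted p-values of these genes ran from 0.00567 to 0.0289. Of the tested genes, 11.6%, 25.8% and 3.89% had no read in sNAM replicates 1, 2 and 3, and Atp6v0d2 had none in 1 of these libraries. Loss of transcripts in these libraries was not told apart from lower expression.

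Of 23 tested genes of perivascular and interstitial macrophages, 2 fell in sNAM, Gas6 and Ednrb, and 1 rose, Timd4. Adjusted over the list alone, 13 were lower and 1 higher. As a set they were lower (camera adjusted p = 5.62e-07; adjusted p = 0.278 with an estimated correlation). The iron, haem and lysosome list had 3 lower genes of 21, Atp6v0d2, Slc40a1 and Lamp1, and 6 lower adjusted over the list alone (camera adjusted p = 7e-04; adjusted p = 0.278 with an estimated correlation). The mannose receptor Mrc1 measured 13080 ± 4690 in sNAM and 38400 ± 4040 in IM and did not pass (adjusted p = 0.083). The microglial gene Tmem119 did not pass either (879.9 ± 499 against 52.43 ± 27.1, adjusted p = 0.0662). None of 23 TGF-β pathway genes was called in limma (camera adjusted p = 0.184). Nor was any of 15 genes of the nerve-associated and microglia-like list called, with 1 higher adjusted over the list alone (camera adjusted p = 0.804). Of 7 tested MHC class II and antigen presentation genes, Cd74 rose, and 3 were higher adjusted over the list alone (camera adjusted p = 0.00368; adjusted p = 0.278 with an estimated correlation). H2-Aa and H2-Eb1 were listed at 0 in every library and H2-Ab1 reached at most 0.78, so the class II α and β chains were not measurable here. None of 21 inflammatory cytokines and chemokines was called over all genes or adjusted over the list alone. Their set was higher (camera adjusted p = 0.00309; adjusted p = 0.278 with an estimated correlation). Il1b measured 153500 ± 48300 against 49160 ± 16400 (adjusted p = 0.116).

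Markers of other cell types moved with this comparison. Dendritic cell markers summed to 2331 ± 534 CPM in sNAM and 633.8 ± 170 in IM, and Ccr7 made up 66.6% of the sNAM mean. Without Ccr7 the sums were 779.5 ± 142 and 608.2 ± 163. As a set of 11 they were higher (2 higher, Ccr7 and Flt3; 3 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.0573 with an estimated correlation). T and NK cell markers summed to 706.6 ± 178 against 431.7 ± 41.8, and without Il7r to 263 ± 224 against 357.5 ± 29.7. Il7r was higher and Cd4 lower, the set of 6 was higher, and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00173; adjusted p = 0.278 with an estimated correlation; 0.0517 without sNAM replicate 3). Mast cell markers were lower as a set (camera adjusted p = 0.0166; adjusted p = 0.505 with an estimated correlation), 1 of 9 lower adjusted over the list alone, but their mean sum was not lower (749.8 ± 1160 CPM in sNAM, 676.6 ± 113 in IM). Their sums in sNAM replicates 1, 2 and 3 were 0.161, 2082 and 167.2 CPM, and the set did not pass without sNAM replicate 1 or 3 (camera adjusted p = 0.955 and 0.168). Neutrophil markers, of which 4 passed the filter and which were not tested as a set, summed to 416 ± 22.1 CPM against 176.2 ± 31.8. Their Il1r2, picked here after its values were seen, measured 4834 ± 2070 against 355.1 ± 167 (adjusted p = 0.0576), and Csf3r 1186 ± 654 against 1392 ± 174. Fibroblast markers summed to 89.07 ± 13.6 CPM against 431.4 ± 92.8, and their set did not pass (camera adjusted p = 0.17). Among them Dcn, a matrix gene, fell from 2626 ± 318 to 186.9 ± 324 (adjusted p = 0.0355), with no read in 2 sNAM libraries. Adjusted over the list alone, 1 fibroblast marker was higher and 1 lower. Monocyte genes did not pass (camera adjusted p = 0.184; 0.023, higher, without IM replicate 2). With fry, perivascular and interstitial genes and iron, haem and lysosome genes passed as lower (fry adjusted p = 0.031 each). Complement and phagocytic receptor genes passed as lower (0.0398) and dendritic cell markers as higher (0.031). The MHC class II and antigen presentation (0.0844), inflammatory (0.261), T and NK cell (0.132) and mast cell (0.132) sets did not pass with fry. In limma with group weights, 91 of 8656 genes passed, 47 higher and 44 lower, and 1297 had an unadjusted p under 0.05. The median log2 difference of all genes was -0.26. No gene passed without sNAM replicate 1 or with a pseudocount of 10, 9 passed without sNAM replicate 3 and 57 without IM replicate 3. Planned edgeR called 367 genes with 31.1% higher, edgeR with the deposited factors 351, DESeq2 922 and limma with a pooled spread 727, against 51.6% higher in the fit with group weights. Voom with quality weights called 107, of which 88.8% were higher, and all 9 calls without sNAM replicate 3 were lower, so the balance of directions depended on the fit.

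**Figure D2:**
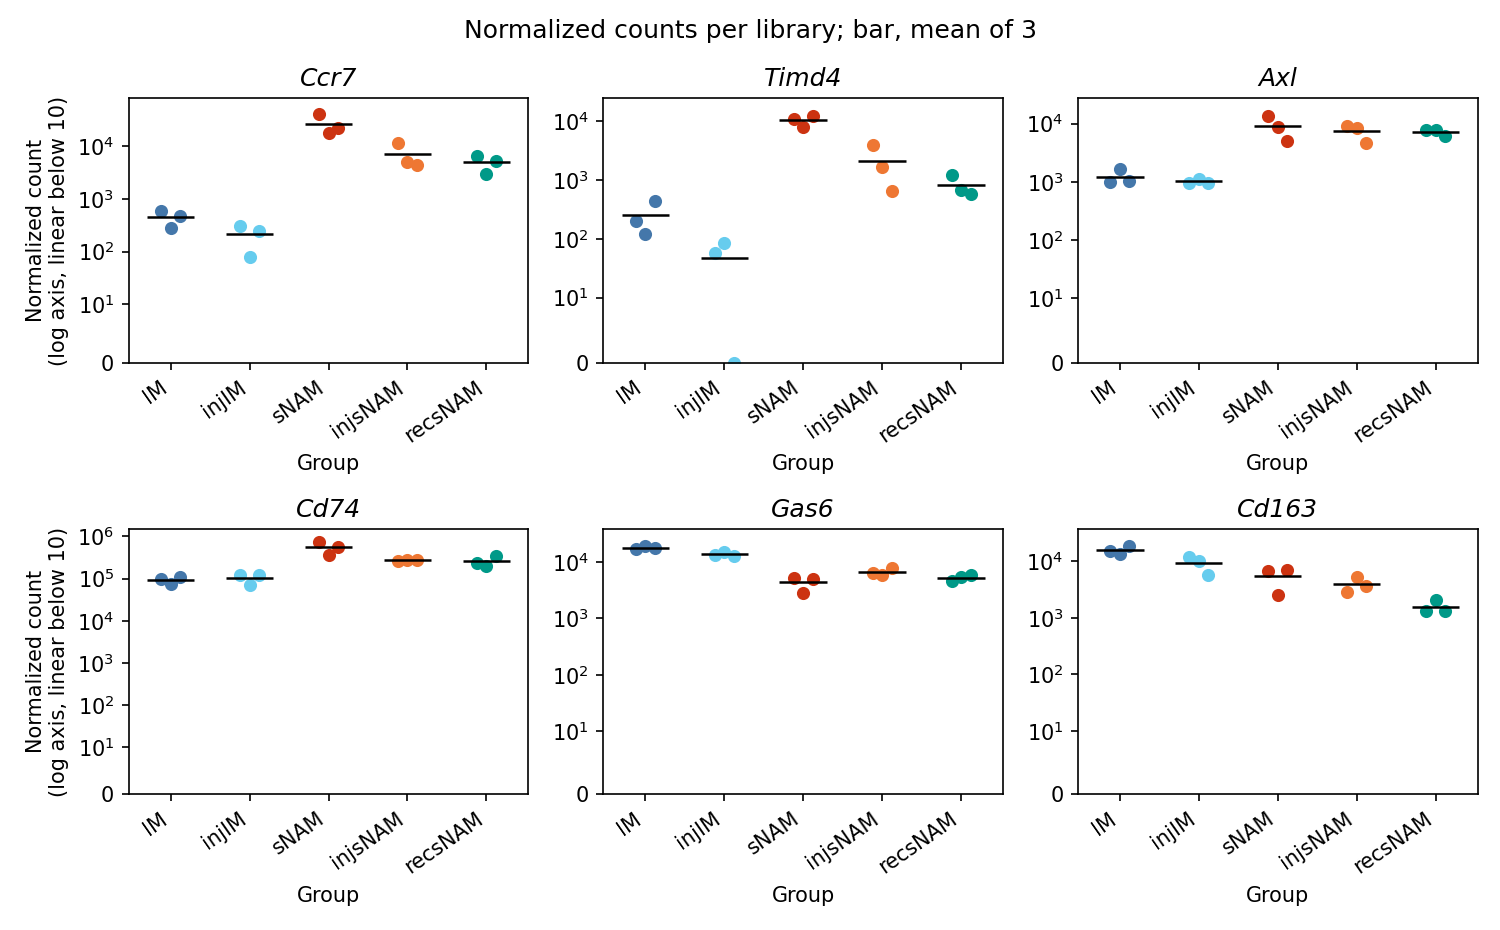
Normalized counts (vertical axis, logarithmic, linear below 10) of 6 genes by group (horizontal axis); each point is 1 library and each bar the mean of 3. Ccr7, Timd4, Axl and Cd74 lie higher in the sNAM, injsNAM and recsNAM libraries than in the IM and injIM libraries, and Gas6 lies lower.

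The comparison of injIM with IM asked how interstitial macrophages differed between the punched and the unpunched ear, a difference called their response below. Their gate, GFP-negative and Tomato-negative, holds no label of when cells arrived. Changes within cells and a change in which cells were present cannot be told apart here. The gelatinase Mmp9 was 70.7-fold higher by group means and varied between the injured libraries (27990 ± 27400 against 396.1 ± 30.4, log2 difference 5.36, SE 0.53, adjusted p = 1.02e-05). Cav1, which forms caveolae, rose from 360.4 ± 142 to 4991 ± 1500 (adjusted p = 7.24e-07), and the secreted phosphoprotein Spp1 from 1156 ± 1380 to 9149 ± 2560 (adjusted p = 0.000946). The membrane glycoprotein Gpnmb rose from 7143 ± 2870 to 21050 ± 5850 (adjusted p = 0.000145) and Arg1, the arginine-degrading enzyme, from 50.51 ± 39.2 to 360.1 ± 189 (adjusted p = 0.00128). The monocyte chemoattractants Ccl2 and Ccl7 fell, Ccl2 from 76070 ± 9800 to 18000 ± 3150 (log2 difference -2.08, SE 0.17, adjusted p = 4.65e-07) and Ccl7 from 65680 ± 13100 to 19290 ± 703 (adjusted p = 1.95e-06). The interleukin-1 genes fell as well, Il1a from 12160 ± 4430 to 2478 ± 351 and Il1b from 49160 ± 16400 to 19150 ± 1570 (adjusted p = 1.26e-06 and 2.72e-05).

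Of 21 inflammatory cytokines and chemokines, 11 fell and none rose, 12 lower adjusted over the list alone (camera adjusted p = 1.56e-12; adjusted p = 0.0228 with an estimated correlation). Of 23 perivascular and interstitial genes, 14 fell and none rose, among them Ccl24 (4473 ± 1160 against 18690 ± 9110), Cd209d and Cd209f. The list had 17 lower adjusted over the list alone (camera adjusted p = 1.64e-13; adjusted p = 0.0385 with an estimated correlation). The lipid handling and damage response list rose in 12 of 26 members and fell in 1. Risen members included the fatty acid carrier Fabp5 (7979 ± 2410 against 2746 ± 228) and the lysosomal protease Ctsd (48110 ± 7810 against 27540 ± 2310). Adjusted over the list alone, 12 were higher and 3 lower (camera adjusted p = 0.000622; adjusted p = 0.0419 with an estimated correlation). Glycolysis and hypoxia genes rose in 6 of 21, 8 adjusted over the list alone (camera adjusted p = 0.000113; adjusted p = 0.0385 with an estimated correlation). The pyruvate kinase Pkm measured 19700 ± 1640 against 12660 ± 1610 and the lactate transporter Slc16a3 1309 ± 179 against 524.6 ± 314. Monocyte genes rose in 6 of 16, 8 adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.0595 with an estimated correlation). In the immediate-early and dissociation stress list, called immediate-early genes below, 9 of 21 genes fell, 11 adjusted over the list alone. The set was lower (camera adjusted p = 1.13e-07, and adjusted p = 0.0599 with an estimated correlation). Among the fallen genes was Nr4a1 (4807 ± 891 against 15970 ± 2730). Stress from cell dissociation was not told apart here from a response to the punch. Of 16 alternative activation genes, 5 fell and 2 rose, Tgm2 and Arg1, with 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00294; adjusted p = 0.0458 with an estimated correlation). Of 22 complement and phagocytic receptor genes, 7 fell and 3 rose, with 9 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0171; adjusted p = 0.0937 with an estimated correlation). In the TGF-β list, 5 of 23 genes rose, among them the transcription factor Bhlhe40 (7283 ± 632 against 2689 ± 395), the integrin subunit Itgav and the inhibitory Smad6, and none fell. Adjusted over the list alone, 6 were higher and 3 lower. The set did not pass, and its median was below 0 where its test pointed up (camera adjusted p = 0.377).

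Markers of other cell types moved here too. Mast cell markers summed to 278.9 ± 4.49 CPM in injIM against 676.6 ± 113 in IM. Of the 9, 8 fell, all 9 adjusted over the list alone (camera adjusted p = 1.47e-10; adjusted p = 0.0385 with an estimated correlation). Dendritic cell markers summed to 303.8 ± 85 against 633.8 ± 170, with 4 of 11 lower, also 4 adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.0385 with an estimated correlation). Langerhans cell markers fell in 1 of 5, Cd207, with 4 adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.091 with an estimated correlation). Neutrophil markers, which include Mmp9, summed to 714.7, 1202 and 3706 CPM in injIM replicates 1, 2 and 3 and to 176.2 ± 31.8 in IM. Mmp9 made up 89.6% of the injIM mean, and without it the sums were 194.6 ± 44.9 and 153.7 ± 30.6. Without IM replicate 2 the complement and Langerhans cell sets did not pass (camera adjusted p = 0.0716 and 0.0845). The nerve-associated and microglia-like list (3 higher and 4 lower of 15) did not pass (camera adjusted p = 0.109). It passed as lower under the block (0.0416) and without IM replicate 2 (0.0337) or injIM replicate 3 (0.0468). Cell cycle genes did not pass either (camera adjusted p = 0.0734). They passed as higher under the block (0.0457) and without IM replicate 2 (0.00701), IM replicate 3 (0.0406) or injIM replicate 1 (0.00614). With fry, the lists that passed with camera passed in the same directions (fry adjusted p from 0.000176 to 0.0199). In limma with group weights, 708 genes passed, 359 higher and 349 lower. Planned edgeR called 3 genes, edgeR with the deposited factors 4, DESeq2 65, limma with a pooled spread 18 and limma without a filter 315. Between 399 and 428 passed without IM replicate 3 (399), IM replicate 1 (425) or injIM replicate 1 (428).

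The comparison of injsNAM with sNAM asked the same of resident nerve-associated macrophages. No gene passed in limma with group weights, where 586 had an unadjusted p under 0.05. Voom with quality weights also called 0, planned edgeR 111, edgeR with the deposited factors 146, DESeq2 725, limma with a pooled spread 363 and limma without a filter 4. The lipoprotein gene Apoe measured 246700 ± 65600 in injsNAM and 65350 ± 30500 in sNAM (log2 difference 1.99, SE 0.52, adjusted p = 0.553). Il1b measured 61520 ± 10600 and 153500 ± 48300 (adjusted p = 0.738), Cd74 269000 ± 8200 and 551800 ± 184000 (adjusted p = 0.879) and Ccr7 7005 ± 3880 and 26810 ± 12500 (adjusted p = 0.756). Dendritic cell markers were lower as a set, with 3 of 11 lower adjusted over the list alone (camera adjusted p = 0.000378; adjusted p = 0.0373 with an estimated correlation). They summed to 794.3 ± 283 CPM against 2331 ± 534, and without Ccr7 to 371.7 ± 108 against 779.5 ± 142. Inflammatory cytokines were lower as a set (camera adjusted p = 1.68e-05; adjusted p = 0.135 with an estimated correlation). Lipid handling genes were higher, 4 of 26 adjusted over the list alone (camera adjusted p = 0.00494; adjusted p = 0.156 with an estimated correlation; 0.0505 without injsNAM replicate 3). Mast cell markers were lower (camera adjusted p = 0.00023; adjusted p = 0.365 with an estimated correlation). That call rested on sNAM replicate 2, at 2082 CPM of them, and ended without it (camera adjusted p = 0.416). Cell cycle genes were higher as a set (camera adjusted p = 0.0201; adjusted p = 0.72 with an estimated correlation), although Mki67 (1833 ± 687 against 2723 ± 1280) and Pcna (935.9 ± 518 against 1182 ± 218) were not. The set did not pass without sNAM replicate 1 (0.0853) or 3 (0.148) or injsNAM replicate 2 (0.304) or 3 (0.0505). Immediate-early genes were lower (camera adjusted p = 0.0391; adjusted p = 0.705 with an estimated correlation). They did not pass without sNAM replicate 1 (0.0677), 2 (0.13) or 3 (0.115) or injsNAM replicate 1 (0.0654) or 2 (0.295). No inflammatory, mast cell, cell cycle or immediate-early gene was called adjusted over the list alone. With fry no list passed in this comparison, the lowest fry adjusted p being 0.106, and inflammatory cytokines were at 0.343. Without sNAM replicate 2, type I interferon genes passed as higher (0.00246, against 0.394 with all libraries) and perivascular and interstitial genes as lower (0.0268, against 0.495). MHC class II and antigen presentation genes did not pass (camera adjusted p = 0.0645; 0.0465, lower, under the block). The difference between the responses of sNAM and IM to injury, tested as an interaction, held no called gene in limma, where 444 had an unadjusted p under 0.05. Voom called 0, planned edgeR 7, edgeR with the deposited factors 31, DESeq2 228, limma with a pooled spread 4 and limma without a filter 6. No gene list passed for the interaction, the lowest camera adjusted p being 0.099, for perivascular and interstitial genes. That list passed without IM replicate 2 (0.0212), injIM replicate 1 (0.0177), sNAM replicate 3 (0.00209) or injsNAM replicate 1 (0.0195). Mast cell markers passed without sNAM replicate 1 (0.00725), and cell cycle genes (0.0214) and dendritic cell markers (0.039) without injsNAM replicate 1. In simulation limma with group weights recovered 1% of 4-fold changes for injsNAM against sNAM and 0% for the interaction, so a count of 0 from this fit does not show that differences were absent. Planned edgeR recovered 31% and 5%, and with these changes planted also called 606 and 33 unchanged genes.

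The comparison of injsNAM with injIM asked which differences between the resident populations were present after injury. Ccr7 was 32.8-fold higher in injsNAM (7005 ± 3880 against 213.8 ± 120, log2 difference 4.45, SE 0.63, adjusted p = 0.00411), and Axl rose to 7420 ± 2460 from 1019 ± 99.5 (adjusted p = 0.00411). Timd4 measured 2095 ± 1720 against 48.03 ± 44.1 (adjusted p = 0.0233) and Clec7a, the β-glucan receptor, 4437 ± 1070 against 1163 ± 57.4 (adjusted p = 0.0233). The lymphocyte genes Cd3g (1436 ± 1160 against 20.1 ± 12.4, adjusted p = 0.046), Cd7, Ctsw and Il2rb were also higher. Lower in injsNAM were Dcn (58.38 ± 101 against 2253 ± 452, adjusted p = 0.00646) and Cav1 (462.7 ± 371 against 4991 ± 1500, adjusted p = 0.0311). The mast cell protease Cpa3 (1.754 ± 2.24 against 909.7 ± 68.4, adjusted p = 0.031) and the semaphorin Sema4b (83.01 ± 41.1 against 974.9 ± 129, adjusted p = 0.0164) were also lower.

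Of 23 perivascular and interstitial genes, Timd4 rose and none fell. Adjusted over the list alone, 5 were lower and 1 higher (camera adjusted p = 6.61e-05, lower; adjusted p = 0.248 with an estimated correlation). The T and NK cell list was higher, with 4 of 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.61e-05; adjusted p = 0.227 with an estimated correlation). Its sum was 702.2 ± 260 CPM against 389 ± 62.8, and without Il7r 401.6 ± 287 against 182.2 ± 44.9. Mast cell markers were lower, 4 of 9 adjusted over the list alone (camera adjusted p = 2.91e-05; adjusted p = 0.227 with an estimated correlation), as were fibroblast markers, 4 of 8 (camera adjusted p = 0.000194; adjusted p = 0.247 with an estimated correlation). Iron, haem and lysosome genes were lower, 4 of 21 adjusted over the list alone (camera adjusted p = 0.000671; adjusted p = 0.248 with an estimated correlation). Growth factor and matrix genes were lower, 2 of 27 (camera adjusted p = 0.0113; adjusted p = 0.227 with an estimated correlation; 0.118 without injsNAM replicate 1). Inflammatory cytokines were higher as a set, 1 of 21 adjusted over the list alone (camera adjusted p = 0.00233; adjusted p = 0.247 with an estimated correlation; 0.159 without injsNAM replicate 3). Il1b measured 61520 ± 10600 against 19150 ± 1570 (adjusted p = 0.0605). Dendritic cell markers summed to 794.3 ± 283 CPM against 303.8 ± 85, and without Ccr7 to 371.7 ± 108 against 291.1 ± 82.8. Ccr7 was the 1 of 11 called, also adjusted over the list alone, and the set did not pass (camera adjusted p = 0.0621). It passed as higher under the block (0.0243) and without injIM replicate 1 (0.0231), injIM replicate 2 (0.038) or injsNAM replicate 3 (0.0302). MHC class II and antigen presentation genes had 3 of 7 higher adjusted over the list alone and did not pass (camera adjusted p = 0.0621). They passed as higher without injIM replicate 1 (0.0497) or 3 (0.0352), and cell cycle genes without injsNAM replicate 1 (0.0116, against 0.253 with all libraries). With fry no list passed in this comparison, the lowest fry adjusted p being 0.0664. In limma, 42 genes passed, 21 in each direction, and 70 with the replicate number as a block. This balance depended on the fit, with 38 of 39 calls higher with voom, 8 of 53 with a pseudocount of 10 and 57 of 74 without injsNAM replicate 2. Without injsNAM replicate 3 only 2 passed, without injsNAM replicate 1 only 6, without injIM replicate 2 20 and without injIM replicate 1 26. In turn, 75 passed without injIM replicate 3 and the 74 without injsNAM replicate 2. Replicates 1 and 3 of injsNAM held T cell transcripts, with Cd3g at 1850 and 2330 against 122 in replicate 2. Whether T cells contributed to the other calls was not tested. DESeq2 called 314, limma without a filter 102, limma with a pooled spread 69 and limma on the 2 groups alone 21.

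The comparison of recsNAM with injIM asked how recruited nerve-associated macrophages differed from interstitial macrophages of the same injured ears. The name recruited rests on the GFP-positive, Tomato-negative gate. No library of that gate came from the unpunched ear, so resident cells without the Tomato label are not excluded from recsNAM. Ccr7 was 23.1-fold higher in recsNAM (4936 ± 1830 against 213.8 ± 120, log2 difference 4.01, SE 0.32, adjusted p = 6.09e-07) and Axl 7.06-fold higher (7200 ± 883 against 1019 ± 99.5, adjusted p = 2.81e-07). Timd4 rose to 828.9 ± 354 from 48.03 ± 44.1 (adjusted p = 0.000111), and the decoy receptor Il1r2 to 1315 ± 472 from 197.3 ± 106 (adjusted p = 0.00026). Il1b rose to 62100 ± 8690 from 19150 ± 1570 (adjusted p = 2.91e-05) and the lipopolysaccharide co-receptor Cd14 to 195900 ± 38300 from 96110 ± 11700 (adjusted p = 0.000141). Mmp9 was lower in recsNAM (537 ± 592 against 27990 ± 27400, log2 difference -5.39, adjusted p = 9.96e-05), as was the collagen-degrading protease Ctsk (2217 ± 901 against 18050 ± 12300). The transferrin receptor Tfrc (630.1 ± 178 against 4468 ± 516) and the haemoglobin scavenger Cd163 (1557 ± 420 against 9054 ± 3130) were lower. Also lower were Gas6 (5266 ± 575 against 13740 ± 1240), the growth factor Igf1 (3326 ± 768 against 7299 ± 747) and Ccl2 (4721 ± 2010 against 18000 ± 3150), and adjusted p-values of the genes from Ctsk to Ccl2 ran from 2.56e-06 to 0.00173.

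Of 23 perivascular and interstitial genes, 19 fell, among them Cd163, Gas6, Ccl7 and Mrc1 (14010 ± 1340 against 26270 ± 5950), and Timd4 rose. Adjusted over the list alone, 20 were lower and 1 higher (camera adjusted p = 9.38e-20; adjusted p = 0.0501 with an estimated correlation). The iron, haem and lysosome list had 6 lower genes of 21, including Tfrc and Atp6v0d2, and 1 higher, the iron carrier Trf (15510 ± 3790 against 7233 ± 1190). It had 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000797; adjusted p = 0.342 with an estimated correlation). Of 21 inflammatory cytokines and chemokines, Il1b rose and 5 fell, among them Ccl2, Ccl3 and Ccl12, with 2 higher and 7 lower adjusted over the list alone. Their set did not pass (camera adjusted p = 0.314; 0.0297, lower, without recsNAM replicate 3). MHC class II and antigen presentation genes rose in 4 of 7, also 4 adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.332 with an estimated correlation). These were Cd74 (258800 ± 79500 against 105700 ± 29300), the class II transactivator Ciita (276.6 ± 27.3 against 112 ± 46.2) and the costimulatory genes Cd80 and Cd86. Growth factor and matrix genes fell in 5 of 27 and rose in 1, with 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.332 with an estimated correlation; 0.0778 without recsNAM replicate 1). Immediate-early genes such as Jun (4097 ± 265 against 8792 ± 1060) and Egr1 fell in 8 of 21 and rose in 3, with 10 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0197; adjusted p = 0.77 with an estimated correlation). That set did not pass without injIM replicate 3 (0.146) or recsNAM replicate 1 (0.078) or 2 (0.313). The TGF-β list had 3 higher genes of 23, Pmepa1, a feedback inhibitor of TGF-β signalling (4541 ± 556 against 1932 ± 242, adjusted p = 0.000596), the ligand Tgfb3 and Id3, and 1 lower, Bhlhe40. Of the 23, 4 were higher and 2 lower adjusted over the list alone, and the set did not pass (camera adjusted p = 0.62). In the nerve-associated and microglia-like list, 4 of 15 rose, among them Tmem119 (1232 ± 449 against 240.5 ± 72.4, adjusted p = 0.000109) and Fcrls (6313 ± 1860 against 2452 ± 897), and 2 fell. Of the 15, 4 were higher and 3 lower adjusted over the list alone. The set did not pass, and its test pointed up where its median and mean were below 0 (camera adjusted p = 0.846).

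Dendritic cell markers summed to 519.3 ± 76.8 CPM in recsNAM and 303.8 ± 85 in injIM, with Ccr7 and Flt3 higher (Flt3 319.9 ± 159 against 44.51 ± 35.4). Without Ccr7, which made up 57.5% of the recsNAM mean, the sum was lower in recsNAM (220.8 ± 36.4 against 291.1 ± 82.8). Of the 11, 2 were higher and 1 lower adjusted over the list alone, and the set did not pass (camera adjusted p = 0.0913; 0.027 without injIM replicate 1). Fibroblast markers were lower, 1 of 8, Dcn, and 3 adjusted over the list alone (camera adjusted p = 0.048; adjusted p = 0.775 with an estimated correlation). The fibroblast set did not pass with the replicate number as a block (0.0632), nor without injIM replicate 3 (0.415) or recsNAM replicate 1 (0.449). Cell cycle genes were higher, 1 of 22, Rrm2, and 0 adjusted over the list alone (camera adjusted p = 0.0495; adjusted p = 0.857 with an estimated correlation), and did not pass without injIM replicate 1 (0.328) or recsNAM replicate 2 (0.89). With fry, the cell cycle (fry adjusted p = 0.614), fibroblast (0.298) and immediate-early (0.066) sets did not pass. Perivascular and interstitial (0.000364), iron, haem and lysosome (0.00565) and growth factor and matrix genes (0.00565) passed as lower with fry. The MHC class II and antigen presentation set, tested without H2-Aa, H2-Ab1 and H2-Eb1, and dendritic cell markers passed as higher (0.0196 each). In limma, 652 genes passed, 276 higher and 376 lower. With the replicate number as a block 1211 passed, 504 higher and 707 lower. Planned edgeR called 10, edgeR with the deposited factors 11, DESeq2 127, limma with a pooled spread 22, limma without a filter 362 and voom with quality weights 989. Without recsNAM replicate 1, 272 passed, and without injIM replicate 1, 357.

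The comparison of recsNAM with injsNAM asked whether recruited and resident nerve-associated macrophages differed after injury. No gene passed in limma with group weights, where 619 had an unadjusted p under 0.05. Voom with quality weights and planned edgeR called 0 as well, edgeR with the deposited factors 8, DESeq2 154, limma with a pooled spread 2 and limma without a filter 12. Ccr7 measured 4936 ± 1830 in recsNAM and 7005 ± 3880 in injsNAM, Axl 7200 ± 883 and 7420 ± 2460, Cd74 258800 ± 79500 and 269000 ± 8200, and Mrc1 14010 ± 1340 and 14630 ± 5440. Ccl7 measured 7061 ± 2690 and 25690 ± 13200 (log2 difference -1.76, SE 0.42, adjusted p = 0.215). Inflammatory cytokines were lower as a set in recsNAM, 5 of 21 adjusted over the list alone (camera adjusted p = 8.96e-06; adjusted p = 0.238 with an estimated correlation). Perivascular and interstitial genes were lower, 1 of 23 (camera adjusted p = 0.000696; adjusted p = 0.521 with an estimated correlation), and so were immediate-early genes, 0 of 21 (camera adjusted p = 0.00164; adjusted p = 0.521 with an estimated correlation). Among markers of other cells, T and NK cell genes were lower, 4 of 6 adjusted over the list alone (camera adjusted p = 0.00018; adjusted p = 0.313 with an estimated correlation). Mast cell genes were higher, 4 of 9 (camera adjusted p = 1.79e-05; adjusted p = 0.313 with an estimated correlation), as were fibroblast genes, 2 of 8 (camera adjusted p = 0.0048; adjusted p = 0.521 with an estimated correlation). Fibroblast genes did not pass without injsNAM replicate 2 (0.0718), perivascular and interstitial genes without injsNAM replicate 3 (0.0719), and immediate-early genes without injsNAM replicate 3 (0.106) or recsNAM replicate 2 (0.0538). With fry no list passed in this comparison, the lowest fry adjusted p being 0.22. Without injsNAM replicate 2, 39 genes passed, and without recsNAM replicate 3, 2 passed. In simulation limma with group weights recovered 22% of 4-fold changes, so a difference that did not pass is not shown to be absent.

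**Figure D3:**
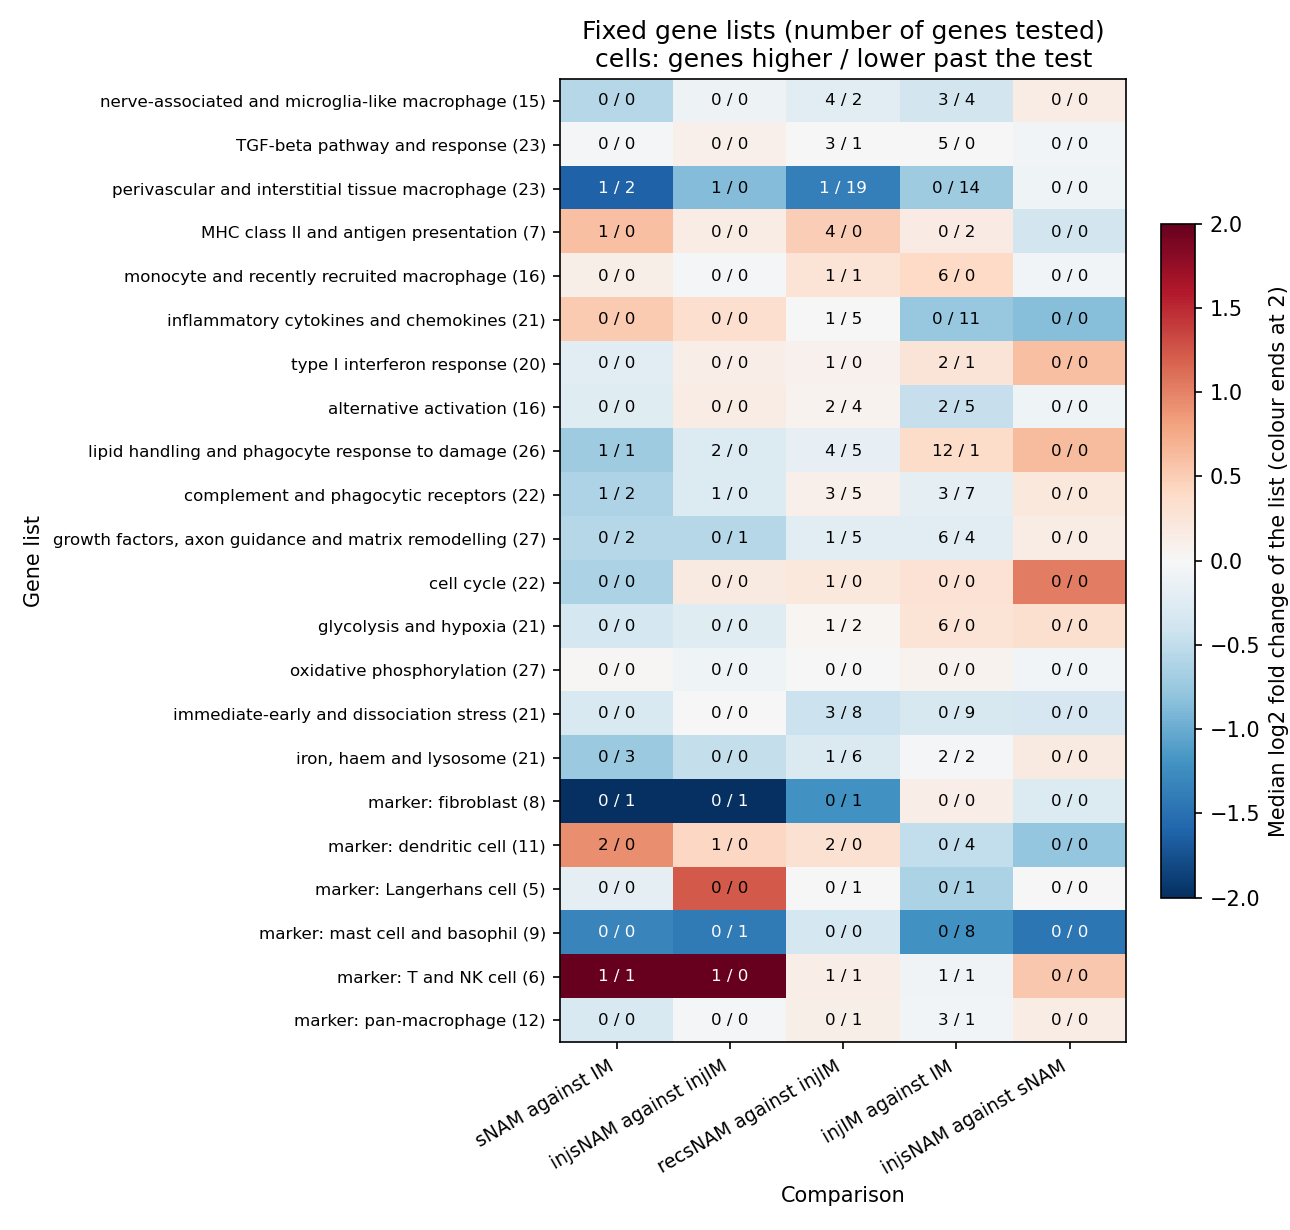
Fixed gene lists (vertical axis, number of tested genes in parentheses) in 5 comparisons (horizontal axis); the colour is the median log2 difference of the list and the pair of numbers gives the genes that passed higher and lower. The perivascular and interstitial list has 19 lower genes in recsNAM against injIM and 14 in injIM against IM.

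The steady-state signature asked whether the differences of sNAM from IM recurred in the injured ear. It held 45 sNAM-high and 36 IM-high genes, chosen on the 6 uninjured libraries alone. Its score was -2.58 ± 0.224 in injIM, 0.249 ± 0.534 in injsNAM and -0.102 ± 0.189 in recsNAM, against -3.14 ± 0.119 in IM and 2.71 ± 0.948 in sNAM, the libraries it was chosen on. The score of every injsNAM and recsNAM library was above that of every injIM library, by 2.83 and 2.48 on average on the log2 scale. With 200 genes in each direction these differences were 1.88 and 1.43. The exact 2-sided permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow, and 0.15 adjusted over 3 comparisons. recsNAM and injsNAM differed by -0.351 (exact 2-sided permutation p = 0.4; 0.4 adjusted), which does not show them equal. This difference was -1.36 with a signature chosen without sNAM replicate 2 and -0.161 without IM replicate 2; without IM replicate 1 or 3 it was -0.214 or -0.175. Of the 45 sNAM-high genes, 44 were higher in injsNAM than in injIM and 44 in recsNAM than in injIM, where 43.1% and 47.2% of all genes were higher. Of the 36 IM-high genes, 35 and 36 were lower. Of these, 9 sNAM-high and 3 IM-high genes passed in injsNAM against injIM and 32 and 30 in recsNAM against injIM, with 0 passing in the opposite direction. The signature rests on sNAM replicates 1 and 3. Without replicate 1 it held 1 gene in each direction, and without replicate 3 it held 0 sNAM-high genes and 1 IM-high gene. These replicates held T cell transcripts, with Cd3e at 1260 and 1800 against 49.5 in sNAM replicate 2. Cd3e was at most 81.4 in the IM, injIM and recsNAM libraries. Whether T cells contributed to the signature was not tested.

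**Figure D4:**
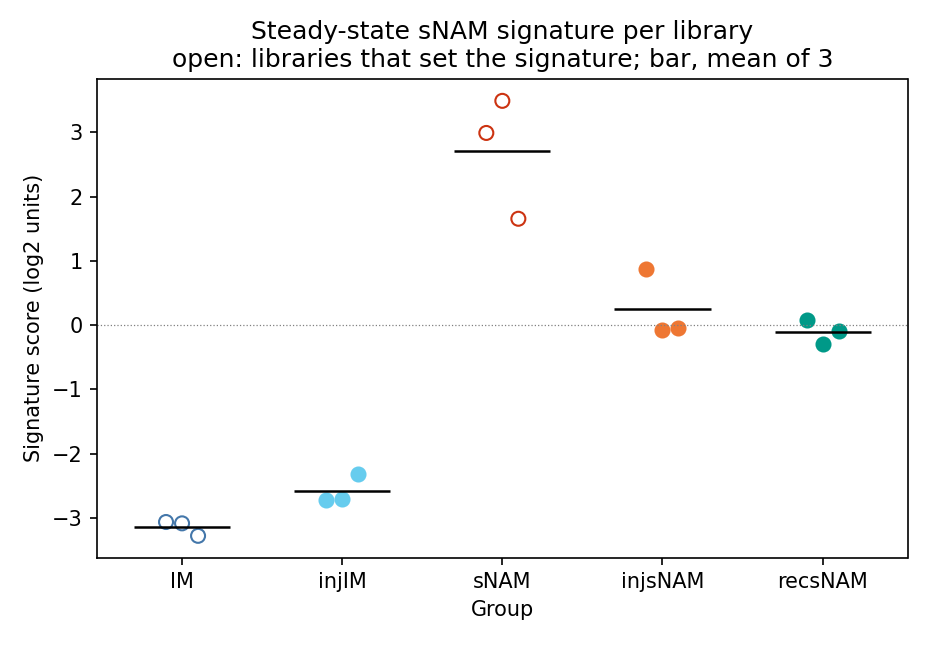
Score of the steady-state signature in log2 units (vertical axis) by group (horizontal axis); each point is 1 library, open for the IM and sNAM libraries on which the signature was chosen, and each bar is the mean of 3. The injsNAM and recsNAM libraries lie between -0.3 and 0.865, above the injIM libraries, of which the highest is -2.32.

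The responses of IM and sNAM to injury were compared across the 8656 genes, from libraries that do not overlap. The log2 differences had a Pearson correlation of 0.261 (jackknife SE 0.0913) and a Spearman correlation of 0.225 across genes, which are not independent replicates. Of the 708 genes that passed in IM, 524 (74%) had the same sign in sNAM, against 57.6% of all genes. With group weights no overlap of called genes could be counted, because that fit called none in injsNAM against sNAM. Overlaps under the fits that called genes there were not counted.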

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

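The edgeR fit as planned, the pooled spread, the pseudocount of 10, TMM scaling and the gene list tests with 1 library left out were chosen as alternatives only after the result was seen; the others were planned. The counts of called genes depended strongly on how the unequal spread of the groups was modelled, and the cause was not tested beyond the simulations. Fits with 1 spread for all groups called more genes in comparisons with sNAM and fewer in comparisons of IM, injIM and recsNAM. Across alternatives, 8 of 184 named gene and comparison pairs were called under every one and 0 reversed direction. These pairs were chosen as called, and every alternative used the same libraries. The 0 therefore says little about direction.

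For sNAM against IM, injIM against IM, injsNAM against sNAM, injsNAM against injIM, recsNAM against injsNAM, recsNAM against injIM and the interaction, in that order, the fit with group weights called 91, 708, 0, 42, 0, 652 and 0 genes. Planned edgeR called 367, 3, 111, 36, 0, 10 and 7; edgeR with the deposited factors 351, 4, 146, 36, 8, 11 and 31; DESeq2 922, 65, 725, 314, 154, 127 and 228. Limma with a pooled spread called 727, 18, 363, 69, 2, 22 and 4, limma without a filter 120, 315, 4, 102, 12, 362 and 6, and limma with a pseudocount of 10 0, 670, 0, 53, 0, 639 and 0. Voom with quality weights called 107, 905, 0, 39, 0, 989 and 0, only the compared groups 81, 527, 0, 21, 0, 462 and 0, and TMM scaling 106, 737, 0, 45, 0, 640 and 0. For sNAM against IM, 51.6% of calls were higher with group weights, 88.8% with voom, 42.5% with TMM and 31.1% with planned edgeR. For injsNAM against injIM, 97.4% were higher with voom and 15.1% with a pseudocount of 10, against 21 of 42 with group weights. Similar counts did not always mean the same genes. Of these 42, planned edgeR called 12 in the same direction, edgeR with the deposited factors 13, voom 20 and TMM scaling 42. Of the 91 for sNAM against IM, they called 54, 57, 54 and 88 in that order.

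With the replicate number as a block, the counts were 100, 928, 0, 70, 0, 1211 and 0, moving by over 1.5 times for injsNAM against injIM and recsNAM against injIM. The numbers are not stated to mark mice. Of 30 pairs of libraries with the same number, 9 deviated together with a correlation over 0.1. The correlation ranged from -0.021 to 0.388, with a median of 0.0649 against -0.0370 for differently numbered pairs. As a hint from the data that libraries of the same number belong together, 14 of 15 libraries correlated best with libraries of their own number. The principal fit left such a pairing out. Gene lists called under the block numbered 7, 13, 7, 8, 6, 6 and 0, against 7, 11, 6, 7, 6, 7 and 0 without it. Of the lists called without the block, 1 was lost, the fibroblast markers of recsNAM against injIM (adjusted p = 0.0632).

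Leaving out 1 library at a time gave 0 (without sNAM replicate 1) to 108 genes for sNAM against IM, 399 (without IM replicate 3) to 827 for injIM against IM, 0 to 0 for injsNAM against sNAM, 2 (without injsNAM replicate 3) to 75 (without injIM replicate 3) for injsNAM against injIM, 0 to 39 (without injsNAM replicate 2) for recsNAM against injsNAM, 272 (without recsNAM replicate 1) to 898 for recsNAM against injIM and 0 to 0 for the interaction. Without sNAM replicate 2, the shallowest library, 82 genes passed for sNAM against IM, 45 of them among the 91 called with all libraries. With an estimated correlation between genes, 0, 7, 1, 0, 0, 0 and 0 gene lists were called. With 1 library left out, 5 to 8, 11 to 13, 4 to 6, 7 to 9, 4 to 6, 4 (without recsNAM replicate 1) to 8 and 0 to 3 (without injsNAM replicate 1) were called. The signature score differences with 200 genes in each direction were 1.43 for recsNAM minus injIM and 1.88 for injsNAM minus injIM, and 88.8% and 89.8% of its genes had the same sign. With 1 uninjured library left out they ranged from 2.09 to 2.51, from 2.28 to 3.45 and, for recsNAM minus injsNAM, from -1.36 to -0.161, with 93.1% to 100% and 95.8% to 97.6% of genes of the same sign; without sNAM replicate 1 or 3 the signature held too few genes for a score. The correlation of injury responses ranged from 0.182 to 0.302 with 1 library left out and was 0.266 for genes of at least 10 CPM. Of the tested genes, 11.6%, 25.8% and 3.89% were at 0 in sNAM replicates 1, 2 and 3, at 18.6, 5.64 and 9.09 M reads. With every library thinned to 5 M reads, 9741, 8425 and 11803 genes were detected in sNAM and 13714 to 14070 in IM, so depth alone does not account for the lower detection.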

Other observations

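The tests of dendritic cells, of library complexity, of T cells, of repeated symbols, of marker sums without 1 gene, of gene lists without 1 library and of the overlap of called genes were chosen only after the result was seen, whereas the counts of other splits were planned. The steady-state differences between nerve-associated and interstitial macrophages recurred in recsNAM as called genes. These comparisons share no library, but they share animals and the same fit. Resident cells without the Tomato label in recsNAM were not excluded and could give the same overlap. Of 47 genes higher in sNAM than in IM, 36 were also called higher in recsNAM against injIM, where independent lists would share 1.5, and of 44 lower genes 23 were also called lower, against 1.91. The genes named here were picked after their values were seen: the shared higher genes include Coro1a and Tmsb4x, which act on the actin cytoskeleton, and the aspartic protease Napsa, and the shared lower genes include the prion protein gene Prnp, the selenium carrier Selenop and the lysosomal protease Ctsl. With injsNAM against injIM, 8 higher genes were shared (Acap1, Axl, Bcl2a1b, Ccr7, Ramp3, Rgs1, Serpinb9 and Timd4; independent lists would share 0.114) and 4 lower genes (Abcd3, Cnrip1, Dcn and Fbln5; 0.107).

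Genes of energy metabolism, the interferon response and Schwann cells were measured as well. None of 27 oxidative phosphorylation genes was called in limma in any of the 7 comparisons, and the lowest camera adjusted p of the list was 0.328. The list passed as higher in injIM against IM without injIM replicate 2 (0.0056) and in recsNAM against injIM without injIM replicate 3 (0.0154). Of 20 type I interferon genes, 2 rose and 1 fell in injIM against IM, and the set did not pass (camera adjusted p = 0.124). It passed as higher without IM replicate 2 (0.00371) or injIM replicate 2 (0.000343), and in injsNAM against sNAM without sNAM replicate 2 (0.00246). Schwann cell markers, of which only 4 passed the filter and which were therefore not tested as a set, summed to 1376 ± 402 CPM in sNAM, 1420 ± 355 in injsNAM and 1078 ± 156 in recsNAM, against 3191 ± 450 in IM and 2629 ± 359 in injIM. Pmp22 alone made up 90.7% of the sNAM mean and 98% of the IM mean, and without it the sums were 127.4 ± 7.08 CPM in sNAM and 63.34 ± 6.46 in IM. The lower sum in sNAM is thus that of 1 gene, and the class is not shown to be lower.

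High Ccr7 and Flt3 in nerve-associated macrophage libraries may come from dendritic cells in the sort gate or from the macrophages themselves. Low complexity of the resident libraries was put to recsNAM against injIM, which hold none of those libraries. Ccr7 was higher there by 4.01 on the log2 scale, with every recsNAM library above every injIM library. Depth was similar, but recsNAM detected fewer genes (14340 ± 665 against 16190 ± 195). Of the tested genes, 0.578% had no read in recsNAM, against 0.212% in injIM and 13.76% in sNAM. Low complexity of the resident libraries thus cannot account for high Ccr7 in recsNAM. For the resident libraries themselves, and for the fewer genes of recsNAM, a part of complexity stays open. Dendritic cells stay open: Fscn1 and Cacnb3, which mature Ccr7-expressing dendritic cells hold, were higher by 0.644 on average (SE 0.209) in recsNAM against injIM, but 0 of the 9 other tested markers passed as higher and their median log2 difference was -0.10. The CD64-positive gate is meant to leave out dendritic cells, but its purity was not tested here, and resident libraries of the same sort held T cell transcripts. Expression by nerve-associated macrophages stays an untested biological alternative.

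T cells in the gate may account for the T cell transcripts of resident nerve-associated libraries. Cd3e, Cd3g, Trdc and Nkg7, markers of T cells in the sorted gate, were all above the highest of the other 9 libraries, or all within their range, in 5 of the 6 resident libraries: all above in sNAM replicates 1 and 3 and injsNAM replicates 1 and 3, none in sNAM replicate 2, and 1 of 4 in injsNAM replicate 2. Cd3e measured 1260, 49.5 and 1800 normalized counts in sNAM replicates 1, 2 and 3 and 2870, 78.4 and 1640 in injsNAM, against at most 81.4 elsewhere, and Nkg7 613, 0 and 1530 and 1910, 0 and 2520, against at most 39.6. The sort was lineage-negative, with the lineage markers not given in the sources used here, and Trdc has a second entry in the table. No biological explanation was tested, and GFP-positive lymphocytes with an active Cx3cr1 locus stay open.

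Several genes that macrophages are known to express, among them Trem2, Aif1, Laptm5, H2-Aa and H2-Eb1, were listed at 0 in every library, as was the ribosomal gene Rps18. A candidate explanation is that reads of symbols listed more than once were lost in the authors' counting. Of 1103 protein-coding symbols with a second entry, 47.3% were at 0 in every library, against 21.6% of the 20268 others (odds ratio 3.26, Fisher's exact test, 2-sided p = 7.76e-75). No biological explanation was tested, and a zero for these genes is not evidence that they were silent.

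Splits of the 6 libraries of each comparison into other groups of 3 number 10, the real one included, too few for a share under 0.05. The real split called 91 genes for sNAM against IM (highest other split 1), 708 for injIM against IM (0), 42 for injsNAM against injIM (0) and 652 for recsNAM against injIM (0), and in each 1 of 10 splits called as many. For injsNAM against sNAM, recsNAM against injsNAM and the interaction the real grouping called 0, a count that each split reaches whatever the data (10 of 10, 10 of 10 and 100 of 100 drawn). These counts therefore say nothing about chance, and the highest other splits called 3, 1 and 17.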
